A study of Homo sapiens with 6 samples.

How the data were processed

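Total RNA of 6 libraries labelled HT1197 was sequenced, 3 after vehicle and 3 after panobinostat, and groups and letters were taken from the labels. The deposited table of counts per gene was made by the authors with featureCounts 1.5.0-p3, per the file headers, and with version 1.5.1, per the submitters' processing notes. Those notes also name Novoalign 2.8, Subread and the build hg38. Per the file headers, reads were assigned by strand (option 2) to Ensembl release 84 genes with the largest overlap, with no option for reads that map to several places. That command lists 9 alignment files, of which 6 have columns here and the rest were not analysed here. The rule by which the authors chose rows is not given in the sources used here: 1245 of the 22718 genes had a total under 10 counts. The deposited FPKM values were the authors' own. Each gene's length was derived from its FPKM in the library where it had the most counts. With that length, each of 64991 FPKM values with 100 counts or more lay within 1% of the count divided by length and column total. The value of that library agrees by construction. The others show that FPKM and scaled counts of a gene are proportional across libraries, so these are the same measurement in another unit.

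Total counts per library ran from 13417898 to 18186087, and a floor of 3 counts stood for 0.165 to 0.224 CPM, a count scaled to the library. Within an arm, libraries correlated at a Spearman rho over genes of 0.977 to 0.986, against 0.934 to 0.943 between arms, and no 2 libraries differed as little as sampling noise alone (chi-square per gene of 2.64 or more). Counting intervals and floors cover counting error only.

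Symbols and GRCh38 coordinates came from GENCODE release 29, which held 22459 of the 22718 identifiers. The release differs from the one used for counting. The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM, and tested with the quasi-likelihood test of panobinostat minus vehicle on the 6 libraries, with no further term. An adjusted p (Benjamini-Hochberg) of 0.05 or less was called a change. The SE of a log2 fold change is its size divided by the square root of the test's F. Means and SDs are of TMM-scaled CPM. Some genes that the rule for named genes takes are not reported here.

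Before the data were examined, 43 gene lists with 947 entries were fixed, of which 784 entries matched a row. Lists with 5 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists. Named genes followed a rule also fixed then. It took the 10 largest rises and the 10 largest falls past the threshold with a mean of 10 CPM or more and arms that do not overlap. From each list it took up to 4 genes past the threshold with the largest change and a mean of 1 CPM or more. A fixed set was HDAC1, HDAC2, HDAC3, HDAC6, CREBBP, EP300, KDM6A, KMT2D, ARID1A, CDKN1A, MKI67, MYC, CD274, B2M, CDH1, VIM, GATA3 and KRT5. Other list members in the text, such as TXNIP, BRCA1, CDKN1B, MYCN, TWIST1, EPCAM, XAF1, KRT8, KRT19, FOXA1, TBX3, PTPRC, CSF1R, CDH5, KDR and LYZ, were chosen after their values were seen. So were the examples from 6 further lists of lineage markers (adrenergic neuroblast, melanocytic, glial, liver and gut, germ cell and pluripotency, simple epithelial). Those lists were written after it was seen which symbols and most abundant genes the table held, so the neuroblast list is not independent of abundance.

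Alternatives were DESeq2 1.42.0, relative log expression size factors, library size alone, upper quartile scaling, no filter, a filter at a mean of 1 CPM, the letter as a block, an adjusted p of 0.01, and each library left out. Limma on log2(FPKM + 1) with a filter at 1 FPKM and without it, and on log2(FPKM + 0.1), served as a check on the other unit. Lists were also tested with an estimated correlation and with fry. The edgeR steps were also run on simulated counts for 16084 genes, of which 200 were changed up or down. They recovered 55.2% of the genes changed 1.5-fold, 85.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 18 false calls. In the data 10482 genes passed the threshold, a far larger share, so these rates do not describe the comparison itself.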

Results

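RNA sequencing measured transcript levels in libraries labelled HT1197, an established line grown from a human bladder carcinoma. The cells had spent 48 hours in vehicle (1% DMSO) or in panobinostat, an inhibitor of the histone deacetylases, at a dose of 2 times the line's half-maximal inhibitory concentration. Each arm held 3 libraries, named by the letters A to C. Vehicle libraries A, B and C held 14287080, 17894568 and 18095984 counts, and panobinostat libraries A, B and C held 13417898, 16205234 and 18186087. The labels describe dishes of 1 line seeded in triplicate and do not tie each library to a dish, so the p-values measure the spread between these samples, which may be technical. The comparison of the arms asks which transcripts differed after the inhibitor.

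DBH, the enzyme that makes noradrenaline from dopamine, fell from 100.5 ± 10.3 CPM (library-scaled counts, mean ± SD, n = 3) to 2.89 ± 0.631 CPM. ADRA2A, an adrenergic receptor, fell from 86.2 ± 6.76 to 12.5 ± 1.83 CPM. LUM, the matrix proteoglycan lumican, rose 59.3-fold, from 2.05 ± 0.335 to 123 ± 4.19 CPM. Of 31 genes of G1/S and DNA replication 26 fell, of 23 spliceosome genes 22 fell, and of 37 ribosomal protein genes 33 rose (adjusted p = 0.192, 0.192 and 0.380 with an estimated correlation). Of the 16084 genes tested, 5416 rose and 5066 fell with panobinostat, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05 or less.

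At least a 2-fold change was seen for 2707 of the genes that rose and 847 of those that fell. The first principal component held 88.7% of the variance and separated the arms. Genes that rose made up 51.7% of the genes changed. With upper quartile scaling they made up 63.2%, since that scaling moved the median log2 fold change of all genes up by 0.14. With library size alone the shift was 0.11. Low-abundance genes rose more often than they fell: of 1662 genes with a mean under 1 CPM, 759 rose and 113 fell. Of 2472 genes with a mean of 100 CPM or more, 560 rose and 1188 fell.

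**Figure D1:**
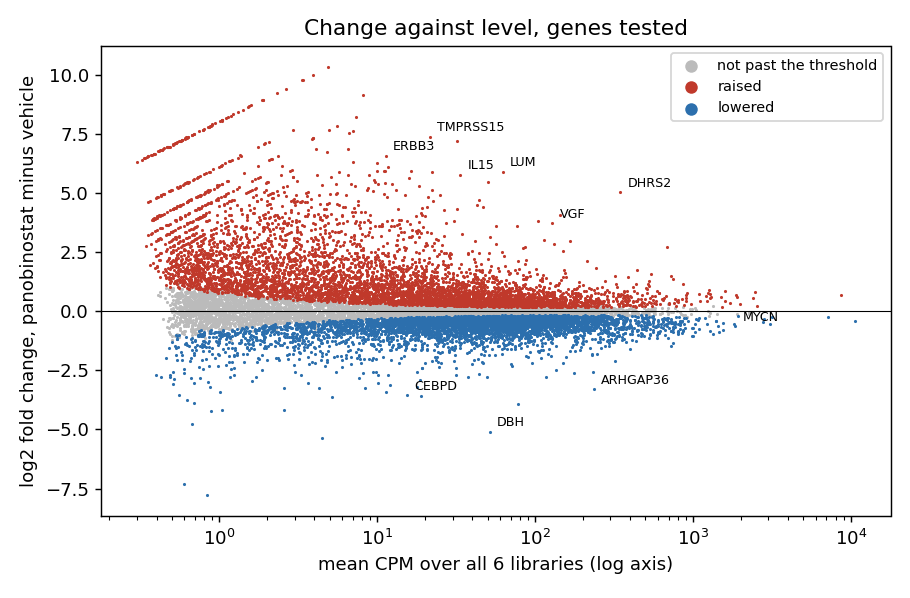
Each point is 1 of 16084 genes tested, with its mean CPM over the 6 libraries on a log axis against its log2 fold change (panobinostat minus vehicle); red points rose, blue points fell and grey points did not pass the threshold. The 1662 genes under 1 CPM hold 759 that rose and 113 that fell, and the straight streaks at the left are genes with few or no counts in the vehicle arm.

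Among genes with a mean of 10 CPM or more, the 10 largest rises included TMPRSS15, FSTL5, ERBB3, CDH12, MYCT1, PLEKHB1, LUM, BLVRB and IL15. TMPRSS15 (ENSG00000154646, chromosome 21, 18269116 to 18485879), the gene of the gut protease enterokinase, rose by 7.38 ± 0.25 on the log2 scale (estimate ± SE) to 42.7 ± 3.81 CPM. ERBB3, a receptor of the EGF receptor family, rose by 6.57 ± 0.26 (adjusted p = 4.05e-11). LUM (ENSG00000139329, chromosome 12, 91102629 to 91111831) rose by 5.89 ± 0.11 (adjusted p = 1.24e-13). IL15, a cytokine of natural killer and T cells, rose from 1.19 ± 0.390 to 65.9 ± 3.20 CPM. These 10 genes stood at 2.05 CPM or less in the vehicle mean, so their folds rest on few vehicle counts: TMPRSS15 had 12 over the 3 libraries and ERBB3 had 11.

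The 10 largest falls included DBH, SLC16A14, CEBPD, ARHGAP36, FAM163A, LRRC4, SPOCK2, IGF2-AS and ADRA2A. DBH (ENSG00000123454, chromosome 9, 133635348 to 133659344) fell by 5.10 ± 0.14 on the log2 scale (adjusted p = 8.94e-13). ARHGAP36 fell by 3.29 ± 0.07, and CEBPD, a C/EBP transcription factor, fell from 28.6 ± 1.26 to 2.40 ± 0.237 CPM. IGF2-AS overlaps other transcripts of its locus, so its level is uncertain. All coordinates are on GRCh38.

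**Figure D2:**
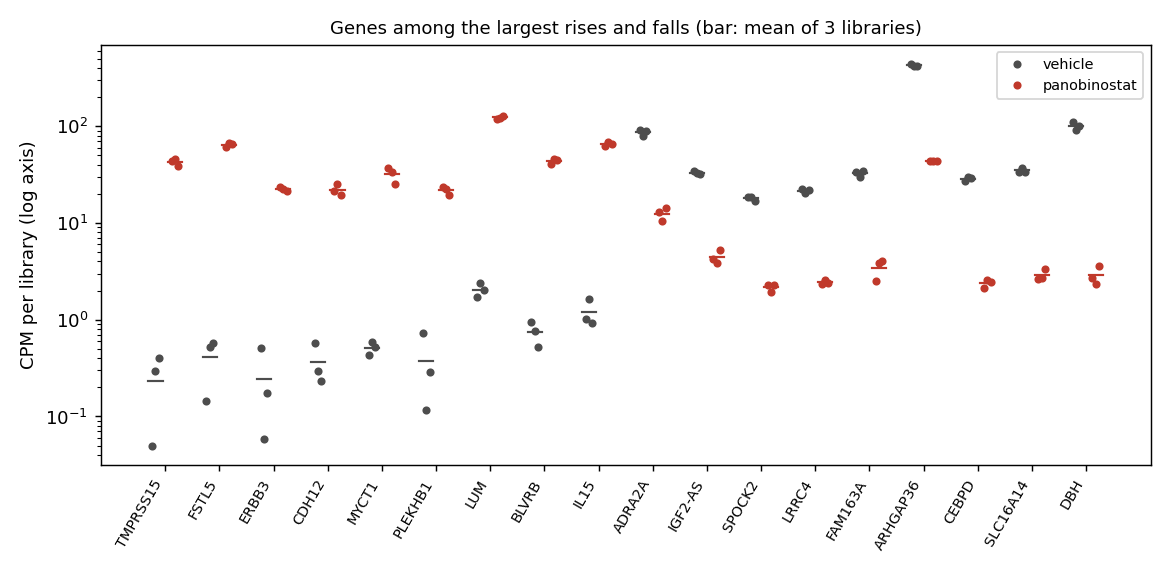
CPM per library on a log axis for 9 of the 10 genes with the largest rises and 9 of the 10 with the largest falls; each point is a library, grey for vehicle and red for panobinostat, and each line is the mean of 3 libraries, with a library at 0 drawn at the bottom. In each of these genes the arms do not overlap, as in LUM at 2.05 against 123 CPM.

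Gene lists fixed before the data were examined were tested with camera at a preset correlation between genes, and 18 of 36 lists passed an adjusted p of 0.05. With an estimated correlation 0 lists passed in camera (9 had an unadjusted p under 0.05) and 31 passed in fry, and the adjusted p with that correlation is given with each of the 18 lists. The adjusted p given for any other list is that with the preset correlation. Counts adjusted over the list alone equalled those over all genes tested, except where both are given. Of all genes with a mean under 1 CPM, 45.7% rose and 6.8% fell. Of those at 100 CPM or more, 22.7% rose and 48.1% fell. The camera test did not match genes for level, so level was not separated from list membership.

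Of 22 genes often raised by HDAC inhibitors, 18 rose and 1 fell (adjusted p = 0.192 with an estimated correlation). DHRS2, a short-chain dehydrogenase, rose from 20.6 ± 4.23 to 671 ± 68.0 CPM. GSN, the actin-severing protein gelsolin, rose by 5.13 ± 0.20 on the log2 scale. GADD45B had 1 count over the vehicle arm and 285 over the treated arm, a ratio of 277 with an exact 95% counting interval of 49.4 to 10996. TXNIP fell by 0.70 ± 0.07. Of 16 deacetylase genes, 5 rose and 3 fell, and adjusted over the list alone 3 rose and 3 fell. HDAC1 rose by 0.40 ± 0.07 and HDAC7 fell by 1.14 ± 0.10. HDAC2, HDAC3 and HDAC6 did not pass, at -0.09 ± 0.08, -0.05 ± 0.07 and -0.08 ± 0.08. The deacetylase list did not pass (adjusted p = 0.705), and its median of -0.08 and mean of 0.02 differed in sign.

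Of 16 chromatin regulators mutated in urothelial carcinoma, 10 fell and 1 rose (adjusted p = 0.599 with an estimated correlation). Without panobinostat library C the list did not pass with the preset correlation either (adjusted p = 0.0585). CREBBP, an acetyltransferase gene, fell by 1.06 ± 0.12 on the log2 scale, and the remodelling ATPase gene SMARCA4 fell by 1.01 ± 0.09. KDM6A (0.06 ± 0.08) and KMT2D (-0.06 ± 0.13) did not pass. EP300 did not pass (-0.28 ± 0.13), but it did without panobinostat library A (-0.45, adjusted p = 0.000894) or vehicle library B (-0.36, adjusted p = 0.0425). ARID1A fell by 0.36 ± 0.13 (adjusted p = 0.0244), and it did not pass without vehicle library A or C or panobinostat library B or C (adjusted p = 0.0704, 0.0876, 0.0899 and 0.114). Its arms overlapped, and the fall did not pass with library size alone or upper quartile scaling (adjusted p = 0.119 and 0.149). With limma on FPKM it did not pass either (adjusted p = 0.24 to 0.296). Of 18 Polycomb and DNA methylation enzyme genes, 10 fell and 1 rose (adjusted p = 0.272 with an estimated correlation). UHRF1 fell by 0.92 ± 0.08 and CBX7 rose by 1.58 ± 0.21.

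Of 31 genes of G1/S and DNA replication, 26 fell and 0 rose (adjusted p = 0.192 with an estimated correlation). MCM5 and MCM7, subunits of the replicative helicase, fell from 282 ± 11.3 to 112 ± 4.04 CPM and from 808 ± 40.3 to 370 ± 37.5 CPM. TYMS, thymidylate synthase, fell by 1.40 ± 0.12 on the log2 scale. Of 27 homologous recombination and Fanconi genes, 17 fell and 2 rose (adjusted p = 0.531 with an estimated correlation). BRIP1 fell by 0.73 ± 0.08 and BRCA1 fell by 0.56 ± 0.08. Of 16 replication-dependent histone genes, 13 fell and 0 rose (adjusted p = 0.531 with an estimated correlation). H2BC4 fell by 1.61 ± 0.10. The histone genes are near-identical copies whose reads can be shared, so their levels are uncertain.

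Genes of later cell cycle stages went both ways: of 30 in G2/M and mitosis, 7 rose, 9 fell and 14 did not pass (adjusted p = 0.388 for the list). CCNB2 fell by 0.62 ± 0.08 on the log2 scale, and CDK1 rose by 0.54 ± 0.09. MKI67 did not pass (-0.12 ± 0.13), though without panobinostat library A it did (-0.32, adjusted p = 0.00671). Among 8 genes of CDK inhibitors, 6 rose and 2 fell, and the list did not pass (adjusted p = 0.325). CDKN2B rose by 1.89 ± 0.20 and CDKN1A (p21) by 0.32 ± 0.09, and CDKN1B (p27) fell by 1.00 ± 0.09.

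Of 23 spliceosome factor genes, 22 fell and 0 rose (adjusted p = 0.192 with an estimated correlation). SRSF2 fell from 612 ± 59.5 to 253 ± 10.8 CPM, and U2AF2 fell by 1.07 ± 0.07 on the log2 scale. Of 30 genes of MYC and ribosome biogenesis, 23 fell and 3 rose (adjusted p = 0.192 with an estimated correlation). UTP20 fell by 1.46 ± 0.08, the nucleolin gene NCL fell by 0.91 ± 0.11, and MYCN fell from 2254 ± 165 to 1451 ± 48.8 CPM. MYC stood near the floor and rose from 0.778 ± 0.152 to 1.54 ± 0.416 CPM (adjusted p = 0.0130), and it did not pass without vehicle library C or panobinostat library A (adjusted p = 0.0621 and 0.0580). With DESeq2 the rise of MYC did not pass either (adjusted p = 0.068). Cytosolic ribosomal protein genes went the other way: 33 of 37 rose and 0 fell (adjusted p = 0.380 with an estimated correlation). RPL27 rose 1.84-fold and RPL11 rose 1.79-fold.

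**Figure D3:**
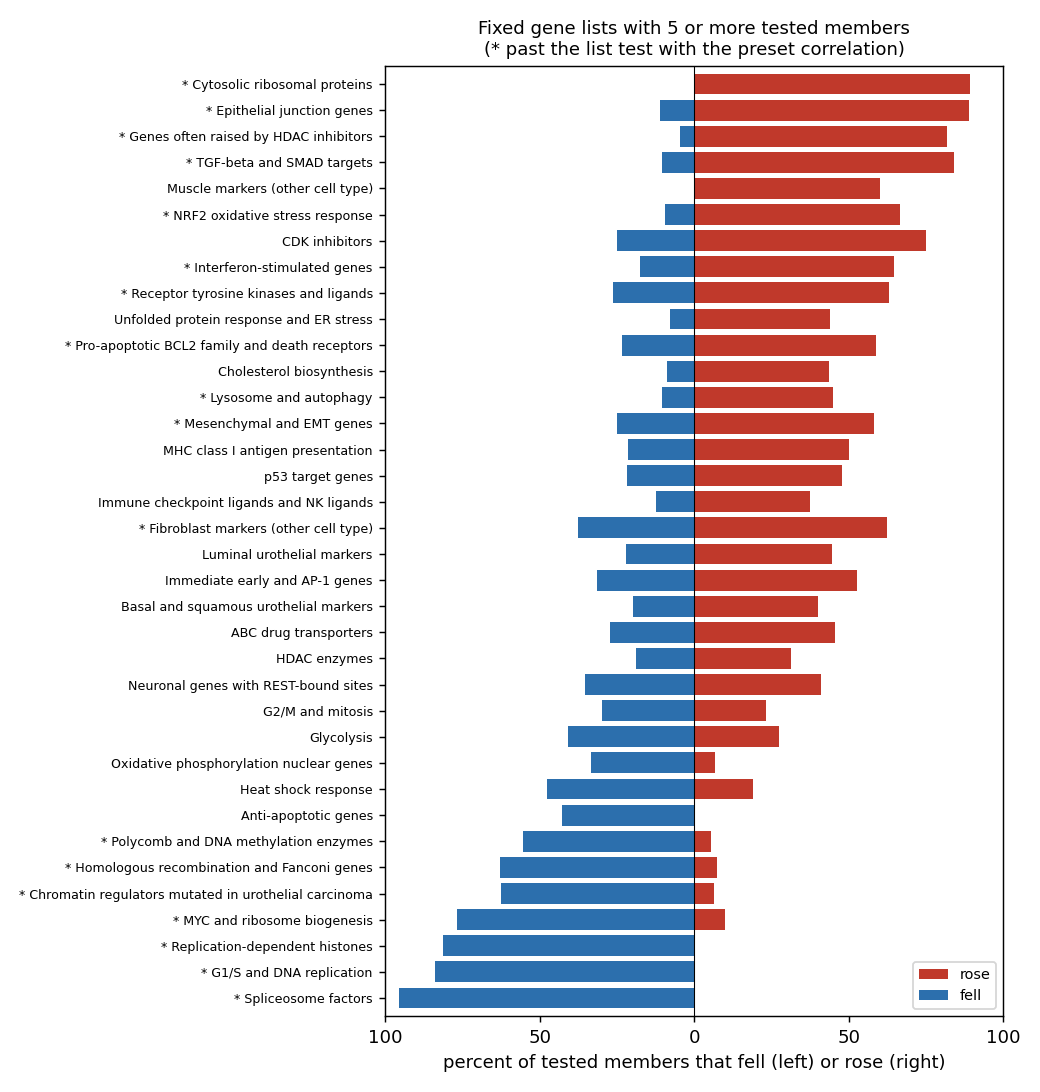
Bars give the percent of each list's tested members that rose (red, right) or fell (blue, left), for the fixed lists with 5 or more tested members; an asterisk marks the 18 lists past the camera test with the preset correlation. Spliceosome factors (22 of 23 fell) and cytosolic ribosomal proteins (33 of 37 rose) lie at opposite ends.

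Of 19 TGF-beta and SMAD target genes, 16 rose and 2 fell, and adjusted over the list alone 17 rose and 2 fell (adjusted p = 0.192 with an estimated correlation). The ligand gene TGFB1 rose 4.67-fold and the receptor gene TGFBR2 rose 8.03-fold. Of 24 mesenchymal and EMT genes, 14 rose and 6 fell, and adjusted over the list alone 14 rose and 7 fell (adjusted p = 0.259 with an estimated correlation). VIM, vimentin, rose from 205 ± 9.37 to 676 ± 12.2 CPM, and the fibronectin gene FN1 rose from 37.8 ± 1.10 to 296 ± 28.3 CPM. TWIST1 fell by 0.90 ± 0.07 on the log2 scale. Of 9 epithelial junction genes, 8 rose and 1 fell (adjusted p = 0.259 with an estimated correlation). CLDN4 rose from 0.584 ± 0.208 to 4.65 ± 0.569 CPM, and EPCAM fell by 0.76 ± 0.24 on the log2 scale.

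Of 17 genes of the pro-apoptotic BCL2 family and death receptors, 10 rose and 4 fell (adjusted p = 0.192 with an estimated correlation). BMF rose from 10.5 ± 0.133 to 93.2 ± 2.10 CPM, and BID fell by 1.51 ± 0.09 on the log2 scale. TNFRSF10B, a TRAIL receptor, had 2 counts in the vehicle arm and 386 in the treated arm, a ratio of 188 with a counting interval of 51.7 to 1557. Of 7 anti-apoptotic genes, 3 fell and 0 rose, among them BCL2 (by 0.85 ± 0.09) and MCL1 (by 0.36 ± 0.08), and the list did not pass (adjusted p = 0.213). Of 23 p53 target genes, 11 rose and 5 fell, and the list did not pass (adjusted p = 0.351). BBC3 rose by 1.37 ± 0.22 and AEN fell by 0.98 ± 0.08.

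Of 17 interferon-stimulated genes, 11 rose and 3 fell (adjusted p = 0.192 with an estimated correlation). IFI6 rose from 2.34 ± 0.283 to 37.7 ± 1.25 CPM, ISG15 rose 16.9-fold, and XAF1 fell by 2.44 ± 0.31 on the log2 scale. Of 14 genes of MHC class I antigen presentation, 7 rose and 3 fell, and the list did not pass (adjusted p = 0.365). B2M rose from 145 ± 5.60 to 242 ± 12.7 CPM, and HLA-C from 0.461 ± 0.317 to 1.60 ± 0.427 CPM. Of the MHC class II list 3 genes were tested, too few for the list test, and all 3 rose. Its median log2 change was 6.57, or 4.82 with a gene at 0 counts set to its bound. In the vehicle arm HLA-DMA had 10 counts, HLA-DPB1 had 1 and the remaining gene had 0. The abundance filter therefore kept these genes through the panobinostat arm. Genes kept that way could hardly fall, so their rises and this median do not describe the list. HLA genes share reads, so their levels are uncertain. Of 8 genes of checkpoint and NK cell ligands, 3 rose and 1 fell (adjusted p = 0.325 for the list), with NECTIN2 rising 10.3-fold. The fall, in CD276, did not pass without vehicle library A or panobinostat library B or C (adjusted p = 0.0684, 0.0554 and 0.0653). Nor did it pass with library size alone, upper quartile scaling (adjusted p = 0.122 and 0.165) or limma on FPKM (0.22 to 0.264). The rise of ULBP1 did not pass without vehicle library B or C or panobinostat library A or B (adjusted p = 0.0625, 0.164, 0.0639 and 0.122). Nor did it pass with DESeq2 (adjusted p = 0.0604) or limma on FPKM (0.0536 to 0.0716). CD274, CDH1 and KRT5, named in advance, were not among the genes kept for testing, so no change is given for them.

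Of 21 NRF2 response genes, 14 rose and 2 fell (adjusted p = 0.196 with an estimated correlation). HMOX1, heme oxygenase, rose 19.5-fold, and AKR1C1 had 0 vehicle counts and was at least 39.6-fold higher against a floor of 3 counts over the arm. Of 29 genes of lysosome and autophagy, 13 rose and 3 fell (adjusted p = 0.264 with an estimated correlation). WIPI1 rose 28.7-fold and the cholesterol transporter gene NPC1 rose 2.26-fold. GABARAPL1 had 3 vehicle counts and 402 treated counts, a ratio of 130.4 with a counting interval of 44.3 to 635. Of 19 receptor tyrosine kinase and ligand genes, 12 rose and 5 fell (adjusted p = 0.192 with an estimated correlation). FGFR4 rose 9.76-fold and ERBB4 rose 3.32-fold.

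Lists of respiration, glycolysis, cholesterol synthesis, protein folding stress, drug transport and immediate early genes did not pass the list test. Of 30 nuclear oxidative phosphorylation genes, 10 fell and 2 rose (adjusted p = 0.213), with NDUFA9 falling by 0.93 ± 0.11 on the log2 scale. Of 22 glycolysis genes, 9 fell and 6 rose (adjusted p = 0.213); GPI fell from 421 ± 26.2 to 183 ± 7.56 CPM and ALDOC rose 3.43-fold. Of 23 cholesterol biosynthesis genes, 10 rose and 2 fell (adjusted p = 0.219), with STARD4 rising from 168 ± 6.01 to 477 ± 15.8 CPM. Of 25 unfolded protein response genes, 11 rose and 2 fell (adjusted p = 0.376), with SEL1L rising 1.92-fold. Of 21 heat shock genes, 10 fell and 4 rose (adjusted p = 0.321); HSP90AA1 fell from 952 ± 107 to 433 ± 57.7 CPM and HSPB1 rose 3.92-fold. In the glycolysis and heat shock lists the median (-0.16 and -0.31) and the mean (0.06 and 0.14) differed in sign. Of 11 ABC transporter genes, 5 rose and 3 fell (adjusted p = 0.325), with ABCB4 rising 21.4-fold. Of 19 immediate early genes, 10 rose and 6 fell (adjusted p = 0.328), with FOS rising 10.4-fold. The metallothionein list had 4 tested genes, too few for the list test; all 4 rose, among them MT2A by 3.13 ± 0.18, and these genes share reads.

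Neuronal genes with REST-bound sites went both ways: of 34, 14 rose and 12 fell (adjusted p = 0.532 for the list). VGF, a secreted neuropeptide precursor, rose from 18.2 ± 2.44 to 238 ± 36.2 CPM, and CPLX2, a synaptic complexin, fell from 536 ± 24.1 to 217 ± 15.5 CPM. The list's median and mean, 0.003 and 0.02, lay above 0 while its test pointed down.

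Of 25 luminal urothelial markers listed, 16 had a row in the table. Since the rule for rows is not given, a missing row is not a measured level. Of those 16, 3 stood at 10 FPKM (a count scaled by gene length and library total) or more with vehicle, namely GATA3, TBX3 and XBP1. KRT8 stood at 0.011 ± 0.004 FPKM with vehicle, KRT19 at 0.278 ± 0.091 FPKM, and FOXA1 had 0 counts in the vehicle arm. GATA3 stood at 35.8 ± 6.21 CPM and did not pass (-0.33 ± 0.15). It passed without vehicle library B (-0.45, adjusted p = 0.0263) or panobinostat library A (-0.53, adjusted p = 0.00147). Of 9 luminal urothelial markers tested, 4 rose and 2 fell (adjusted p = 0.229 for the list). PPARG rose from 3.48 ± 0.224 to 8.59 ± 0.517 CPM. Of 30 basal and squamous markers listed, 12 had a row, and of the 5 tested 2 rose and 1 fell (adjusted p = 0.551). DSC3 rose 3.69-fold and DSC2 fell by 1.13 ± 0.09 on the log2 scale.

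A list of 24 adrenergic neuroblast markers was written once it was seen which symbols and which most abundant genes the table held, so its high levels are in part built in. Of these genes 21 stood at 10 FPKM or more with vehicle. MYCN stood at 832 ± 67.3 FPKM, CHGA at 322 ± 7.31, HAND2 at 238 ± 10.9 and PHOX2A at 139 ± 16.8. With panobinostat 16 of the 22 tested fell and 2 rose, as they did adjusted over the list alone. ISL1 fell by 1.05 ± 0.07 on the log2 scale and CHGA rose 1.34-fold.

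**Figure D4:**
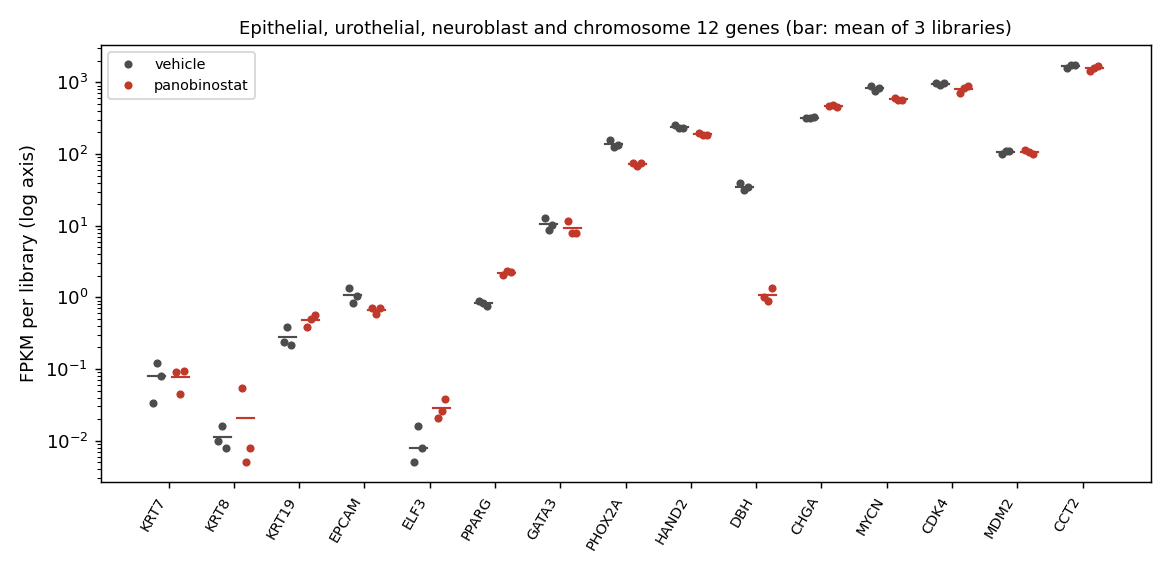
FPKM per library on a log axis for epithelial, urothelial, neuroblast and chromosome 12 genes, chosen after their values were seen; points are libraries, grey for vehicle and red for panobinostat, and lines are means of 3, with a library at 0 drawn at the bottom. KRT8 lies at 0.011 FPKM and MYCN at 832 FPKM in the vehicle mean.

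Lists of other cell types were tested in the same way. Of 8 fibroblast markers, 5 rose and 3 fell (adjusted p = 0.192 with an estimated correlation); COL1A1 rose 13.5-fold and FBLN1 fell from 162 ± 12.6 to 82.4 ± 2.18 CPM. Of 5 muscle markers 3 rose and 0 fell (adjusted p = 0.351), with CNN1 rising 4.93-fold. Lists with under 5 tested members had no list test. Of 3 leukocyte markers 2 rose (PTPRC and CSF1R) and LYZ fell, and of 3 endothelial markers CDH5 and KDR rose. Of 3 NF-kB genes NFKB2 rose and NFKBIA fell, and of 3 cancer-testis genes PRAME fell by 0.43 ± 0.07 on the log2 scale. Mitochondrially encoded transcripts were not analysed here.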

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

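The number of genes changed, 10482, ranged from 7808 to 11788 over the alternatives, and no gene called in the main test was called in the other direction under any of them. DESeq2 gave 10354 genes, of which 9563 were shared. Leaving out each library in turn gave 9568 to 10668 genes. Counts of at least 2-fold changes were smaller with limma on FPKM, where the pseudocount shrinks the folds of low genes: 930 rose and 288 fell with log2(FPKM + 1), 1387 and 456 with log2(FPKM + 0.1), and 1078 and 289 with log2(FPKM + 1) and no filter. The 18 lists past the camera test became 0 with an estimated correlation and 31 with fry, which does not compare a list with other genes, and they numbered 17 to 18 with a library left out. Of the 173 named genes under the alternatives, 2843 values kept their call, 32 lost it (in ULBP1, CD276, MYC and ARID1A) and 10 gained one (in EP300, KDM6A, MKI67 and GATA3), and the cause was not tested. Whether the letters pair the libraries was not settled. Deviations of same-letter libraries correlated at 0.081 (A), -0.021 (B) and 0.104 (C) over genes, and those of different letters at -0.119 to 0.047. With the letter as a replicate block 10541 genes changed, and EP300 and GATA3 passed. In each arm libraries A and C correlated best with their own letter, and library B did not. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 10482 genes and was the 1 split to reach that number, and the highest of the others gave 0. Each other split mixed libraries of both arms, so the difference between the arms added to the spread within its groups. Their counts of 0 are therefore no measure of chance. Depth limits genes near the floor of 3 counts, for which folds are bounds or counting ratios.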

Other observations

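Of 2402 tested genes with a vehicle mean under 1 CPM, 1566 rose and 38 fell, a class in which the abundance filter favours rises. Markers of other lineages lay on both sides of that level with vehicle, so the rate is no baseline for their lists, which were written after it was seen which genes the table held and had no list test. All 5 melanocytic markers tested, of 10 listed, rose: PMEL rose by 4.06 ± 0.13 on the log2 scale (n = 3) and went from a mean of 3.99 to one of 71.6 FPKM, and TYRP1 went from 0.505 ± 0.027 to 6.80 ± 0.617 FPKM. All 5 glial markers tested, of 10 listed, rose, with BCAN going from 0.648 ± 0.154 to 4.83 ± 0.553 FPKM, and S100B stands in both lists. Of 4 germ cell and pluripotency markers, SOX2 rose 18.2-fold, LIN28B fell from 43.8 ± 3.32 to 17.8 ± 1.07 FPKM and 2 did not pass. Of the liver and gut markers 1 was tested, AFP, and it rose 8.50-fold from 4 vehicle counts. Of 20 simple epithelial markers listed, 10 had a row and 3 were tested, of which CLDN4 rose and EPCAM fell. These counts were the same adjusted over the list alone.

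Of 732 lincRNAs 346 rose and 99 fell, of 796 antisense RNAs 325 rose and 116 fell, and of 12988 protein-coding genes 4356 rose and 4620 fell. Level was not separated from gene type: of all genes under 1 CPM 45.7% rose, and of those from 1 to 10 CPM 43.9%. From 3 counts or fewer over the vehicle arm, 360 genes reached 30 or more over the panobinostat arm, and 4 genes made the opposite move. Log2 fold change hardly followed gene length, as derived from the FPKM, over all genes tested (Spearman rho of -0.058 across genes, which are not independent replicates).

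The tests on the lineage of the vehicle libraries were chosen after the result was seen. KRT8 and KRT19, in the luminal list fixed in advance, were at or under 0.383 FPKM in the vehicle libraries. A mixture with epithelial urothelial cells is argued against by KRT8 and KRT19, abundant in such cells, which stayed at or under 0.565 FPKM in the 6 libraries. A urothelial line that had lost its epithelial genes in culture stays open, since of the urothelial factors GATA3, PPARG, FOXA1 and ELF3 only 1, GATA3, stood at 10 FPKM or more, and GATA3 is also in the neuroblast list. Libraries of a cell line other than an epithelial urothelial one cannot be told apart from such a loss, because low keratins go with both and the neuroblast list was written knowing the most abundant genes; no biological explanation was tested.

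Genes of low mean expression rose more often than they fell. The choice among the scalings tried is argued against as the source: the median log2 fold change of genes under 1 CPM was 0.76, and the largest shift between them was 0.14. All of these scalings rest on the counts alone, so a change in total RNA per cell is not covered and stays open. Carried-over DNA in the treated libraries would add a similar FPKM to each near-silent gene. Over 829 such protein-coding genes the 10th, 50th and 90th percentiles of the gain were 0.0184, 0.0863 and 0.461 FPKM, so the upper gains go against it as the only source; the 10th percentile was 0.213 of the median, between the bounds set in advance, and a part from this source cannot be told apart from a release of silent genes by the inhibitor. That release, the effect the design names, stays open as untested.

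Neighbouring genes on chromosome 12 were among the most abundant transcripts with vehicle. The highest median over 7 neighbouring protein-coding genes was 6.74 on the log2(FPKM + 0.1) scale, above the 6.62 that 95% of 1000 shuffled gene orders stayed under, though the highest shuffled order reached 7.32. The region, on chromosome 12 from 68686734 to 69601570 (GRCh38), holds MDM2, YEATS4 and CCT2 at 107, 545 and 1711 FPKM, and a second lies at 122207663 to 122827528. This is consistent with a raised copy number of the region, as a hypothesis that RNA alone cannot settle. Around MYCN on chromosome 2 the highest such median was 4.99, under that 6.62, although MYCN and its neighbour DDX1 stood at 832 and 132 FPKM. The next genes, NBAS and CYRIA, stood at 28.5 and 31.7 FPKM. A median over 7 genes cannot show a raised level of only a few of them, so it does not decide on a narrow region around MYCN.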
